A study of Mus musculus with 15 samples.

How the data were processed

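RNA sequencing libraries were made from cells of a mouse pancreatic acinar line, grown as monolayers in medium with 10% fetal bovine serum, per the labels' protocols. The cells were held for 24 h in stripped medium and then for 24 h with a ligand, and RNA was extracted with TRIzol reagent. The labels give no ligand concentrations. They also leave open the library kit, any selection of polyadenylated RNA, the sequencing batch, and whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The 15 libraries fall into 5 groups of 3 by the treatment in the labels: the vehicle DMSO, AM580, CD3254, AM580 and CD3254 together, and 9-cis retinoic acid.

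The deposited table holds raw read counts per Ensembl gene for the 15 libraries, with no normalization. Per the submitters' processing notes the tools were FastQC, HISAT2 2.2.1, SAMtools 1.18 and HTSeq, with the mm10 genome build. The strand setting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. Near-identical paralogs such as Acot1 and Acot2 may share reads, and their values are uncertain. Of 43432 gene identifiers in the table, 42462 matched a symbol in the gene name table. Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names, and may differ slightly from the annotation release behind the counts. The counter's 5 categories of reads without a gene stayed out of library sizes and tests. They held from 18.1% to 28.5% of the reads in 14 libraries and 63.0% in replicate 3 of 9-cis retinoic acid. All columns of the table were used.

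Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 16736 genes, libraries were scaled by TMM factors, and quasi-likelihood models with robust estimation were fitted to all 15 libraries together, which share 1 estimate of the spread. Each of 10 contrasts was tested two-sided, with Benjamini-Hochberg adjustment within the contrast and a threshold of 0.05, written here as FDR. The contrasts were each ligand treatment against DMSO, the joint treatment against either agonist alone, the 2 x 2 interaction, 9-cis retinoic acid against the joint treatment and against AM580, and AM580 against CD3254. The interaction is the log2 change with AM580 in the presence of CD3254 minus the log2 change with AM580 in its absence. Levels are given as CPM, counts scaled to a common library total with the TMM factors, as mean ± SD of 3 libraries. Fold changes are fitted log2 values with a standard error (SE) derived from the F statistic, and intervals are at 95%.

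The samples, tests, gene lists, the rule for naming genes and the first set of other settings were fixed before the data were examined. After the data were seen, a second fit was added. The sign of the first principal component of log2 CPM (prior count 2) parted 5 libraries, 1 of each treatment, from the other 10, and this library set entered the model as a term. The set was read from the same counts, so its p-values rest on a term defined on the data they test, and no p-value of a gene between the sets is reported. The residual degrees of freedom were 10 without the term and 9 with it. The median tagwise biological coefficient of variation was 0.305 without the term and 0.193 with it. The median SE of a log2 fold change against DMSO was between 0.337 and 0.338 without the term and between 0.220 and 0.222 with it. Fits of the 10-library set alone give within-set values, and the 5-library set holds 1 library per treatment, so it gives differences without a test.

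Named genes are, per contrast, those past the threshold with a mean of at least 1 CPM and no overlap between the libraries compared, the 6 largest changes each way for the comparisons with DMSO and of 9-cis retinoic acid with the joint treatment and the 4 largest for the others. Members of a described list with the smallest adjusted p were added, and 20 receptor, retinoid, lipid and pancreas genes were named in advance. Predicted gene models were not named. The same rule was also applied to the fit with the library set term, and list members were named by their p adjusted over the list alone. Both of those choices were made after values were seen.

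A total of 20 gene lists were tested over 8 contrasts with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 160 tests. Camera with an estimated correlation stands beside it. Fry is given only as the number of calls that held, 11 of 35, so a list described below may not pass it. The lists held targets of the retinoic acid receptors, of the liver X receptors, of the peroxisome proliferator-activated receptors (PPAR) and of other partners of the retinoid X receptors, retinoid metabolism, nuclear receptors and cofactors, acinar enzymes, acinar transcription factors, ductal and progenitor markers, endocrine markers, stellate and fibroblast markers, leukocyte and endothelial markers, Hox genes, cholesterol synthesis, the unfolded protein response, interferon-stimulated genes, immediate early and heat shock genes, readouts of TGF-beta, Wnt and Notch signalling, the cell cycle, and mitochondrially encoded transcripts. They came from textbook knowledge and not from these samples.

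The deposited counts of replicates were compared pairwise. The chi-square per degree of freedom lay between 17.3 and 676 over the 15 pairs, so no pair matched within sampling noise and no library was counted as a duplicate. The fit was tested on simulated counts for the joint treatment against DMSO with 16518 genes. Without the library set term 12% of genes changed 2-fold and 57% of those changed 4-fold were recovered, with 0 false calls. With it the shares were 46% and 83%, with 6 false calls among 140. The counts were drawn from the fit with the term, including its difference between the sets and its spread. The true set was then given to the model with the term, so its higher shares are partly built in. They do not test a set read from the counts themselves.

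Other settings tried were DESeq2 median-ratio size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter and a stricter filter on low counts (1 CPM in 3 libraries and a mean count of 50), fits of only the groups compared, the replicate number as a block, and leaving out each library. Added after seeing the data were the library set term, the 10-library set alone, leaving out both AM580 replicate 1 and 9-cis retinoic acid replicate 3, and offsets for GC content and transcript length (99.2% of tested genes had both). Comparisons that share the DMSO libraries were set beside 20 simulations of unchanged groups.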

Results

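Transcript levels were measured by RNA sequencing in cells of an acinar line from a mouse pancreatic tumour after 24 h with ligands of the retinoid receptors. The retinoic acid receptor RARα binds DNA as a heterodimer with a retinoid X receptor (RXR), and the series set out to study how ligands of the partners influence each other across the genome. Cells received the vehicle DMSO, AM580 (an agonist selective for RARα), CD3254 (an RXR agonist), AM580 and CD3254 together, or 9-cis retinoic acid, which binds receptors of both families. Each treatment had 3 libraries. The reads assigned to genes numbered between 28501170 and 46801058 in 14 libraries and 14600962 in replicate 3 of 9-cis retinoic acid, and 16736 genes were tested.

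The libraries did not group by treatment. The first principal component carried 48.3% of the variance and parted DMSO replicate 1, AM580 replicate 1, CD3254 replicate 1, replicate 2 of the joint treatment and 9-cis retinoic acid replicate 1 from the other 10 libraries. These 5 lay between -90.0 and -59.4 on that component and the other 10 between 25.3 and 40.2. The labels name no batch, and the 5 libraries hold 1 of each treatment, so each comparison is given in the planned fit, without this library set, and in a fit with it as a term, which was added after the data were seen. Replicate 3 of 9-cis retinoic acid lay apart on the second component, at 97.1, and 17.3% of its gene counts fell on rRNA-like genes, against at most 1.96% in any other library.

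**Figure D1:**
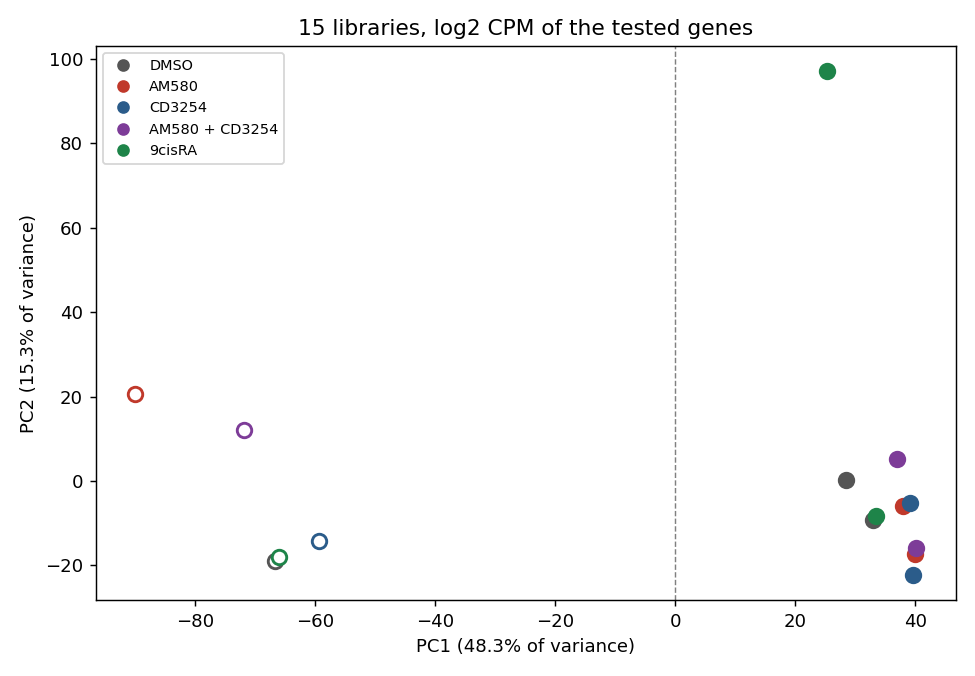
Each point is 1 of 15 libraries on the first and second principal components of log2 CPM, in arbitrary units, with colours for the treatments and open symbols for the 5-library set. The 5 open points lie between -90.0 and -59.4 on the first component, and 9-cis retinoic acid replicate 3 lies at 97.1 on the second.

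Genes that recur below are given here with GRCm38 coordinates. The retinoid genes were Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908), whose cytochrome P450 degrades retinoic acid, Dhrs3 (ENSMUSG00000066026, chromosome 4, 144892827 to 144928209), which encodes a retinaldehyde reductase, and Rarb (ENSMUSG00000017491, chromosome 14, 16430839 to 16819156), which encodes RARβ. Fmo5 (ENSMUSG00000028088, chromosome 3, 97628804 to 97655282) encodes a flavin-containing monooxygenase and Enpp1 (ENSMUSG00000037370, chromosome 10, 24637914 to 24712159) an ectonucleotide pyrophosphatase. The NAD-hydrolysing ectoenzyme CD38 is encoded by Cd38 (ENSMUSG00000029084, chromosome 5, 43868553 to 43912375). The lipid genes were Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830), for a secreted inhibitor of lipoprotein lipase, Cpt1a (ENSMUSG00000024900, chromosome 19, 3322334 to 3385733), for the carnitine palmitoyltransferase of fatty acid import into mitochondria, and Abcg1 (ENSMUSG00000024030, chromosome 17, 31057675 to 31117988), for a cholesterol efflux transporter. All are protein-coding, and the counts sum reads over each gene without resolving its exons.

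The comparison of AM580 with DMSO asked what the RARα agonist alone changed. In the fit with the library set term 5 genes rose and 0 fell. Cyp26b1 rose 13.3-fold, from 0.307 ± 0.315 to 3.84 ± 2.65 CPM (SD, n = 3 in each group), with a log2 change of 3.73 ± 0.36 (SE, edgeR FDR = 0.000594). Dhrs3 rose 5.62-fold, from 3.80 ± 1.34 to 23.3 ± 15.1 CPM (FDR = 0.000537), and Fmo5 rose 3.26-fold, from 3.72 ± 0.569 to 12.6 ± 3.89 CPM (FDR = 0.00277). Cd38 rose 4.56-fold (FDR = 0.0262) and Enpp1 rose 1.94-fold (FDR = 0.0171). Rarb stood at 1.96 ± 0.581 CPM against 0.332 ± 0.112 CPM, with a log2 change of 2.56 ± 0.44 and an FDR of 0.105.

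Among 29 measured targets of the retinoic acid receptors, 22 had a fold above 0 and 7 below with AM580, and the list was higher than other genes (camera adjusted p = 4.9e-07, and adjusted p = 0.0026 with an estimated correlation). Adjusted over the list alone, 4 members rose without the library set term, which were Rarb, Cd38, Cyp26b1 and Dhrs3, and 6 with it, where Epha2 and Gprc5a joined them. Over all genes tested, 0 and 3 members passed. Retinoid metabolism was also higher (adjusted p = 9.8e-05, and adjusted p = 0.032 with an estimated correlation, or 0.056 with that and the library set term together). Its members past 0.05 adjusted over the list alone, with the term, were Cyp26b1, Dhrs3, Adh1, an alcohol dehydrogenase at a log2 change of 0.95 ± 0.16, and Rbp2, a cellular retinol-binding protein at 1.08 ± 0.32. Cyp26b1 and Dhrs3 belong to both lists, so the calls of the lists are not independent, here and in the other comparisons.

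Without the library set term, 0 genes passed for AM580, with 204 at an unadjusted p under 0.05, a smallest FDR of 0.473, and 10 calls by DESeq2. Unchanged genes would put a share of 0.05 of the 16736 genes tested under that threshold. Each such count given, here and below, in either fit, was lower, except the 940 genes for the joint treatment against AM580 with the term. The lower counts are no sign of further changes, but they do not exclude them. Without the term the spread also holds the difference between the library sets, so counts there can fall below that share. In the 10-library set alone some counts were above it, such as 1124 for the joint treatment against DMSO and 2069 for 9-cis retinoic acid against the joint treatment. Whether the higher counts reflect further changes was not tested. With the term, Enpp1 and Cd38 lost their calls when any 1 of the 3 DMSO libraries or AM580 replicate 2 or 3 was left out, up to an FDR of 0.20, and leaving out DMSO replicate 1, DMSO replicate 3, AM580 replicate 2 or AM580 replicate 3 left 3 genes. In the 10-library set alone, 3 genes passed, which were Dhrs3, Fmo5 and Rarb (FDR = 0.0298, 0.0298 and 0.0439), and Cyp26b1, Enpp1 and Cd38 did not (FDR = 0.0905 for Cyp26b1). The log2 change there was 4.18 for Cyp26b1 and 2.25 for Dhrs3, while the single pair in the 5-library set differed by 3.29 and 2.94.

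**Figure D2:**
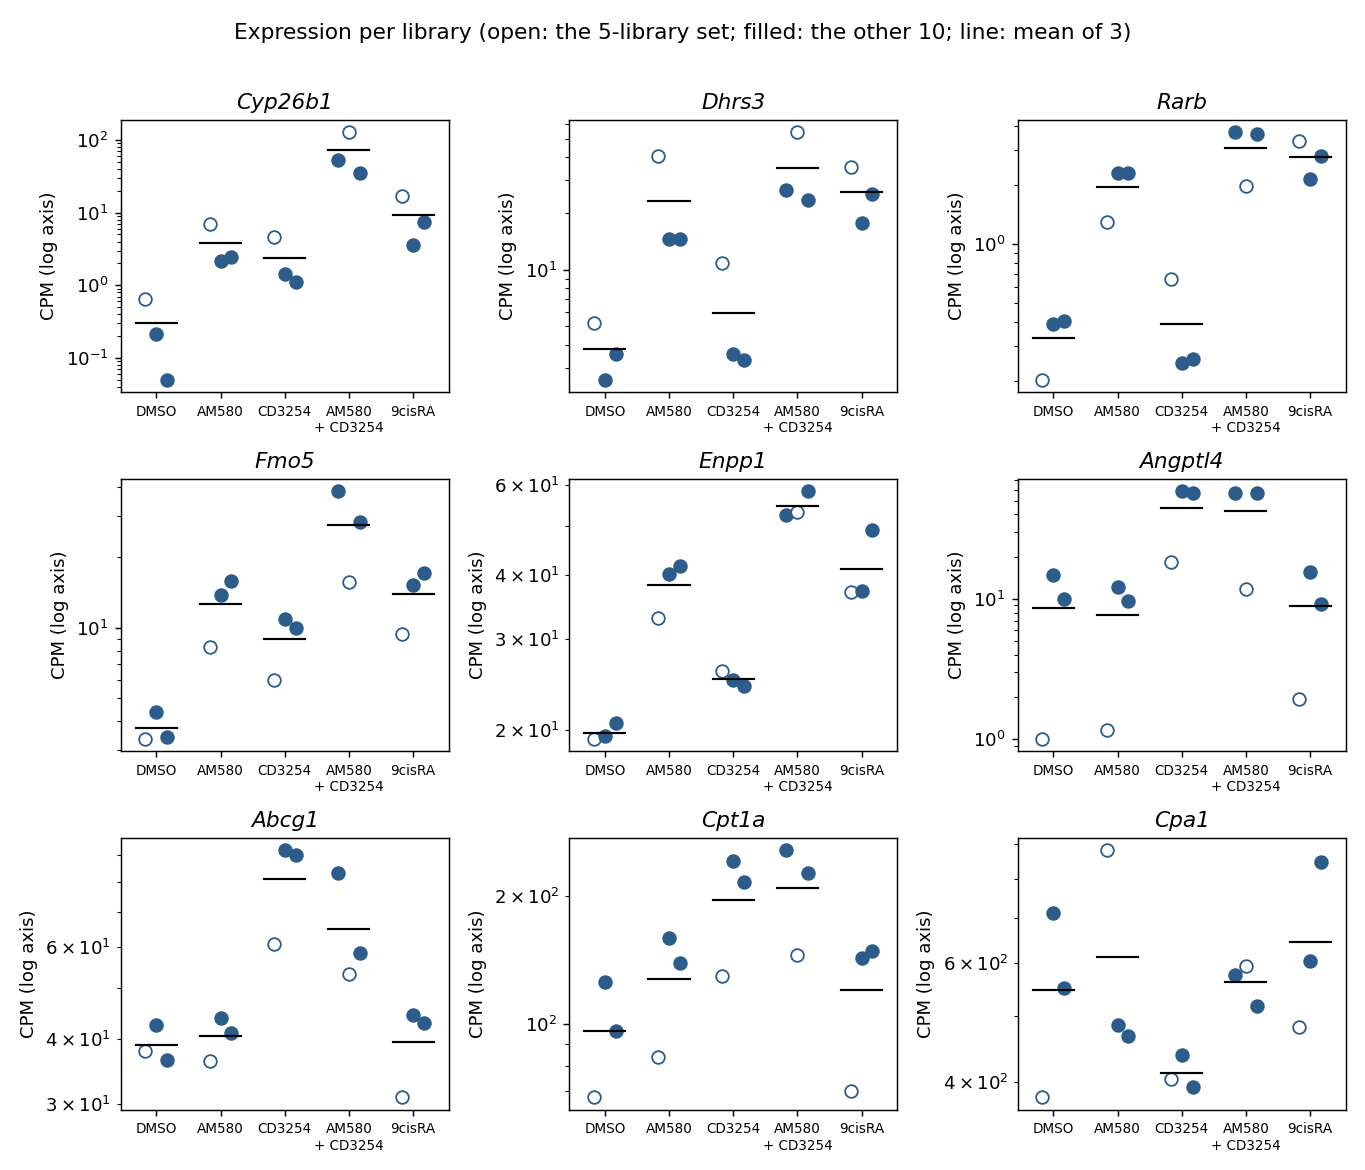
Each panel plots 1 gene in CPM on a log axis for the 5 treatments, with 1 point per library, open for the 5-library set and filled for the other 10, and a line at the mean of 3. Cyp26b1 reached 35.5 to 127 CPM with both agonists and stayed between 0.0503 and 0.659 CPM in DMSO.

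The RXR agonist CD3254 alone was compared with DMSO next. With the library set term 4 genes rose and 0 fell. Angptl4 rose 6.96-fold, from 8.66 ± 7.05 to 44.7 ± 22.8 CPM (log2 change 2.80 ± 0.34, edgeR FDR = 0.0105), Cpt1a rose 2.01-fold, from 96.5 ± 29.1 to 196 ± 58.3 CPM (FDR = 0.0146), and Abcg1 rose 2.04-fold, from 39.0 ± 3.18 to 80.9 ± 17.4 CPM (FDR = 0.0382). Cyp26b1 rose 7.92-fold, to 2.41 ± 1.96 CPM (FDR = 0.0105). Dhrs3, at 5.91 ± 4.28 CPM, and Rarb, at 0.389 ± 0.237 CPM, did not pass, with log2 changes of 0.48 ± 0.22 and 0.23 ± 0.48.

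Liver X receptor targets were the list with the smallest p under CD3254, and 20 of 24 had a fold above 0 (camera adjusted p = 1.1e-23, and adjusted p = 0.00034 with an estimated correlation). Adjusted over the list alone, 5 members rose without the library set term and 10 with it, against 0 and 1 over all genes. With the term they included the cholesterol transporter genes Abca1 (log2 change 1.25 ± 0.29), Abcg1 and Abcg5 (2.11 ± 0.50), the lipoprotein lipase gene Lpl (1.33 ± 0.34), the acyl-CoA synthetase gene Acsl3 (1.04 ± 0.24), and Srebf1, for a lipogenic transcription factor (0.67 ± 0.20). PPAR targets were higher too, with 27 of 30 folds above 0 (adjusted p = 3.3e-13, and adjusted p = 0.0014 with an estimated correlation). Of these 6 rose with the term adjusted over the list alone, among them Angptl4, Cpt1a, and Pdk4, a pyruvate dehydrogenase kinase gene, at 1.02 ± 0.301 CPM against 0.229 ± 0.103 CPM. Retinoid metabolism was higher (adjusted p = 0.00074, and adjusted p = 0.042 with an estimated correlation, or 0.16 with that and the term together). Its members past 0.05 adjusted over the list alone, with the term, were Cyp26b1 and Lpl, which is also among the liver X receptor targets. The list's call ended without DMSO replicate 1 (camera adjusted p = 0.119, without the term). That fit leaves DMSO with no library of the 5-library set, so the set may also move this value.

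For CD3254 without the term, 0 genes passed in edgeR and 0 in DESeq2, with 76 at an unadjusted p under 0.05. With the term the count fell to between 0 and 2 whichever of the 6 libraries was left out: 0 without DMSO replicate 1 or 3, 1 without DMSO replicate 2 or CD3254 replicate 1 or 2, and 2 without CD3254 replicate 3. Cpt1a and Abcg1 lost their calls in all 6 of these fits, Cyp26b1 in 5 and Angptl4 without DMSO replicate 1 or 3, at FDR values of up to 0.222, 0.495, 0.119 and 0.199. The 10-library set alone gave 0 calls, and 13 genes passed with the term when AM580 replicate 1 and 9-cis retinoic acid replicate 3 were left out. Within that set the log2 changes were 2.21 for Angptl4 and 1.04 for Cpt1a against differences of 4.12 and 0.95 in the 5-library set.

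Joint treatment with AM580 and CD3254 was compared with DMSO to see what both agonists changed together, and it gave the most calls. Without the library set term 3 genes rose and 0 fell, and with it 21 rose and 0 fell. Cyp26b1 rose to 71.8 ± 48.3 CPM, at a log2 change of 7.85 ± 1.06 without the term (edgeR FDR = 0.0240) and 7.98 ± 0.38 with it (FDR = 9.7e-08), a fitted 252-fold change that rests on DMSO counts of 2 to 26 reads. Fmo5 rose 6.95-fold with the term, to 27.4 ± 11.3 CPM (FDR = 1.2e-05), and Enpp1 rose 2.77-fold, from 19.7 ± 0.729 to 54.7 ± 3.19 CPM (FDR = 0.000109). Both also passed without the term, at FDR values of 0.0240 and 0.00472. Dhrs3 rose 8.82-fold to 34.8 ± 16.8 CPM (FDR = 1.2e-05), and Rarb rose 9.27-fold to 3.10 ± 0.978 CPM (FDR = 0.00679) with the term. The largest other changes were in the teneurin gene Tenm1 (28.7-fold, FDR = 0.0149) and in Itga2, for the integrin α2 subunit (19.0-fold, FDR = 0.00475). The fold of Tenm1 rests on DMSO counts of 1 to 8 reads and joint levels of 1.30, 3.05 and 5.64 CPM, and its call was lost without any 1 DMSO library or joint replicate 3 (FDR up to 0.141).

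Further genes that rose with both agonists and the term were Cd38 (5.75-fold), Angptl4 (5.71-fold), Adh1 (2.50-fold) and Cpt1a (2.17-fold), with FDR values of 0.00344, 0.00523, 0.00263 and 0.00263. The remaining 10 were Nqo2, Pde7b, Fam151a, H19, Chd1l, Pim3, Zim1, Nrp2, Serpina6 and Colgalt2, named here for completeness after their values were seen, with log2 changes between 0.83 and 2.53. Targets of the retinoic acid receptors (21 of 29 folds above 0, camera adjusted p = 3.9e-12), of the liver X receptors (19 of 24, adjusted p = 1.5e-14) and of PPAR (25 of 30, adjusted p = 4.7e-07) were all higher, with adjusted p = 0.00049, 0.0012 and 0.011 with an estimated correlation. For PPAR targets that p was 0.063 when the term was added. Adjusted over the list alone with the term, 4, 11 and 5 members rose, and over all genes 4, 0 and 2. Retinoid metabolism was higher as well (adjusted p = 2.7e-05, and adjusted p = 0.025 with an estimated correlation), although its median log2 change was -0.05 and its mean 0.51, and the members that moved were Cyp26b1, Dhrs3 and Adh1.

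The 3 calls without the term became 0 without any 1 of the DMSO libraries, 1 without replicate 1 of the joint treatment and 2 without replicate 2 or 3, and 5 genes rose and 1 fell without AM580 replicate 1, 5 rose without CD3254 replicate 1 and 1 rose without AM580 replicate 2 or 9-cis retinoic acid replicate 3. With the term the count was between 11 and 17, with 13 without DMSO replicate 1 or without joint replicate 1 or 3 and 11 without DMSO replicate 3, and Cyp26b1, Fmo5, Dhrs3, Enpp1, Cpt1a, Nqo2, Adh1, Cd38 and Itga2 passed in each of those 6 fits. In the 10-library set alone 12 genes rose and 1 fell, and with the term 81 rose and 28 fell when AM580 replicate 1 and 9-cis retinoic acid replicate 3 were left out, and 62 rose and 32 fell by DESeq2. Without the term DESeq2 gave 15 higher and 4 lower. Cpt1a did not pass in the 10-library set (FDR = 0.0548). There the log2 change of Cyp26b1 was 8.44, of Dhrs3 3.03 and of Enpp1 1.47, and the pair of libraries in the 5-library set differed by 7.48, 3.35 and 1.47.

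**Figure D3:**
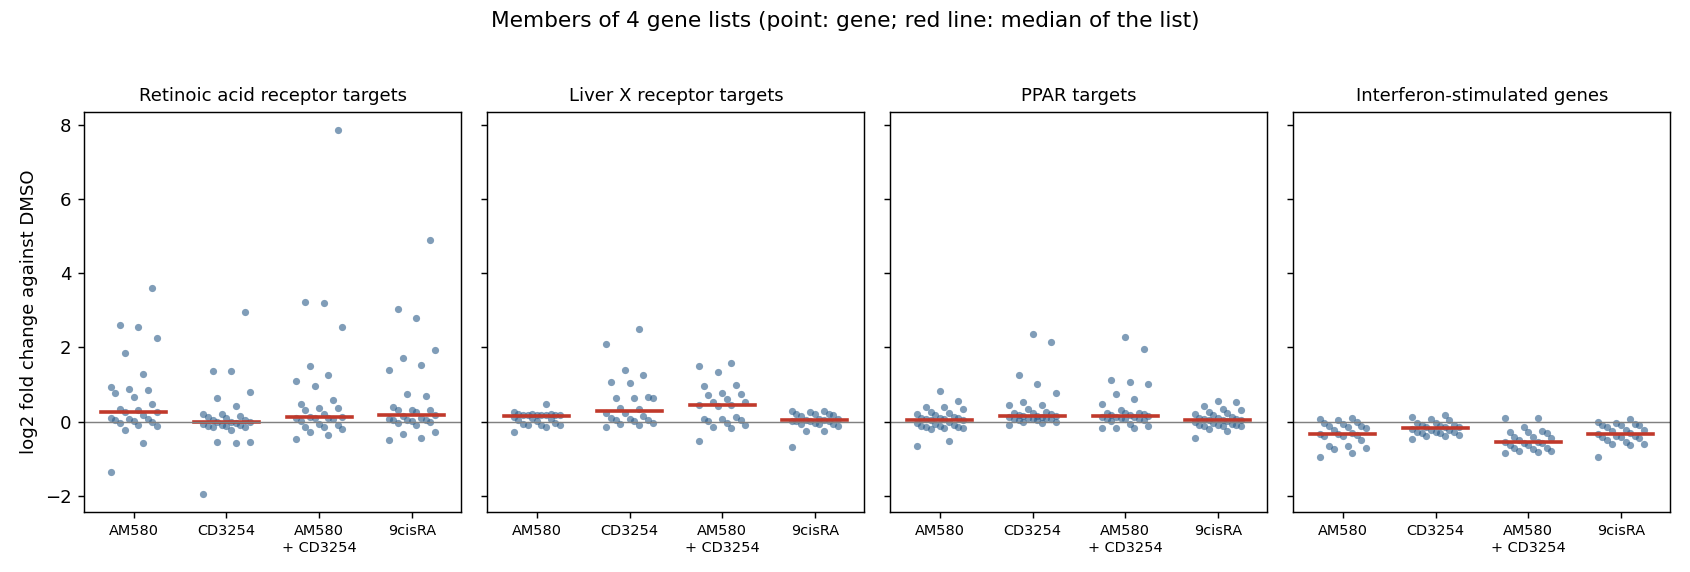
Each point is a member of 1 of 4 gene lists, placed by its log2 fold change against DMSO in the fit without the library set term for 4 treatments, with a red line at the list's median. Retinoic acid receptor targets spread furthest upward with both agonists, up to 7.85 for Cyp26b1, and 22 of 24 interferon-stimulated genes lay below 0 there.

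9-cis retinoic acid was compared with DMSO as a single ligand of both receptor families. With the library set term 5 genes rose and 0 fell. These were Cyp26b1 (30.8-fold, to 9.24 ± 6.80 CPM, edgeR FDR = 3.4e-05), Dhrs3 (6.93-fold, to 26.2 ± 8.71 CPM, FDR = 7.5e-05), Fmo5 (3.60-fold, to 13.9 ± 4.06 CPM, FDR = 0.00118), Enpp1 (2.08-fold, FDR = 0.00579) and Rarb (8.40-fold, to 2.77 ± 0.593 CPM, FDR = 0.0296). The lipid genes that rose with CD3254 did not pass: the log2 change was 0.20 ± 0.33 for Angptl4 and -0.01 ± 0.15 for Abcg1. Targets of the retinoic acid receptors were higher, with 22 of 29 folds above 0 (camera adjusted p = 2.7e-10, and adjusted p = 0.00088 with an estimated correlation), and 4 members rose adjusted over the list alone, which were Rarb, Cd38, Cyp26b1 and Dhrs3, with 3 over all genes when the term was in the model. Retinoid metabolism was higher (adjusted p = 0.00055, and adjusted p = 0.042 with an estimated correlation, or 0.056 with the term as well). That call ended without DMSO replicate 1 (camera adjusted p = 0.0705, without the term), a fit that leaves DMSO with no library of the 5-library set.

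Without the term 0 genes passed for 9-cis retinoic acid, with 243 at an unadjusted p under 0.05 and 10 calls by DESeq2. With the term, Enpp1 lost its call without any 1 DMSO library (up to FDR = 0.0916), Rarb without any 1 DMSO library or replicate 1 or 3 of 9-cis retinoic acid (up to FDR = 0.309), and 3 genes passed without DMSO replicate 1 or 3. Without AM580 replicate 1 and 9-cis retinoic acid replicate 3, 12 genes passed with the term. The 10-library set alone gave 4 calls, without Enpp1 (FDR = 0.114), with log2 changes of 5.35 for Cyp26b1 and 2.80 for Dhrs3 against differences of 4.56 and 2.73 in the 5-library set.

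What CD3254 added in the presence of AM580 was read from the joint treatment against AM580 alone. With the library set term 2 genes rose and 0 fell: Cyp26b1 rose 19.0-fold (log2 change 4.25 ± 0.29, edgeR FDR = 1.4e-05) and Angptl4 rose 6.16-fold (2.62 ± 0.34, FDR = 0.0172). Liver X receptor targets were higher (15 of 24 folds above 0, camera adjusted p = 5.3e-06, and adjusted p = 0.021 with an estimated correlation, or 0.11 with the term as well), with Abca1, Acsl3, Abcg1, Lpcat3, Lpl, Scd2, Elovl5 and Abcg5 past 0.05 adjusted over the list alone in the fit with the term. PPAR targets were higher at the preset correlation (adjusted p = 0.0039, and adjusted p = 0.11 with an estimated correlation), a call that ended without AM580 replicate 2 or 3 or without joint replicate 1 or 2 (adjusted p up to 0.146). Without the term 0 genes passed, with 229 at an unadjusted p under 0.05 and 1 by DESeq2. With the term 940 genes had an unadjusted p under 0.05 in edgeR, more than the share of 0.05 expected of unchanged genes. The Angptl4 call ended when any 1 of the 6 libraries was left out, at FDR values between 0.0744 and 0.245, leaving 1 gene each time. In the 10-library set alone 2 genes passed, with a log2 change of 4.26 for Cyp26b1, and the 5-library pair differed by 4.19.

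What AM580 added in the presence of CD3254 was read from the joint treatment against CD3254 alone. With the library set term 5 genes rose and 0 fell: Cyp26b1 (31.8-fold, edgeR FDR = 2.9e-06), Dhrs3 (6.31-fold, FDR = 0.000103), Fmo5 (3.00-fold, FDR = 0.00343), Enpp1 (2.18-fold, FDR = 0.00343) and Rarb (7.89-fold, FDR = 0.0310). Targets of the retinoic acid receptors were higher, with 23 of 29 folds above 0 (camera adjusted p = 1.5e-14, and adjusted p = 0.00034 with an estimated correlation). With the term 5 members rose adjusted over the list alone, which were Cyp26b1, Dhrs3, Rarb, Cd38 and Tgm2, and 3 over all genes. Nuclear receptors and cofactors were higher, with 25 of 27 folds above 0 and Rarb as the member that passed (adjusted p = 3.0e-05, and adjusted p = 0.029 with an estimated correlation, or 0.16 with the term as well). Rarb belongs to both of these lists. Without the term 0 genes passed, with 107 at an unadjusted p under 0.05 and 8 by DESeq2. The count with the term was 3 without CD3254 replicate 2 and 2 without CD3254 replicate 3, and Rarb lost its call without either of these or joint replicate 1 or 3 (FDR up to 0.518). Enpp1 lost its call without CD3254 replicate 2 or 3 and Fmo5 without CD3254 replicate 3 (FDR up to 0.0606 for both). In the 10-library set 5 genes passed, Enpp1 not among them (FDR = 0.0639), with a log2 change of 2.87 for Dhrs3 against a difference of 2.31 in the 5-library pair.

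The interaction between AM580 and CD3254 asked whether the joint change departed from the sum of the single log2 changes, which bears on influence between the partners of the heterodimer. It gave 0 calls without the term (99 genes at an unadjusted p under 0.05, edgeR, and 0 by DESeq2) and 0 with it (332 genes, smallest FDR 0.961, and 0 by DESeq2), and 0 of the 20 gene lists. Cyp26b1 had an interaction of 1.26 ± 0.48 on the log2 scale with the term (95% interval 0.23 to 2.30 before adjustment, FDR = 0.961), so its joint level lay 2.40 times above the product of the single folds, a departure that did not hold up after adjustment over all genes. The value was 0.94 in the 10-library set and 1.46 among the single libraries of the 5-library set. For Dhrs3 the interaction was 0.17 (interval -0.49 to 0.82), for Fmo5 -0.12 (-0.69 to 0.45), for Enpp1 0.17 (-0.22 to 0.56), for Rarb 0.42 (-0.91 to 1.75) and for Angptl4 -0.18 (-1.15 to 0.80). Cd38 had -1.02 (-1.93 to -0.10, FDR = 0.961). The median SE of an interaction over all genes was 0.477 without the term and 0.312 with it.

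9-cis retinoic acid was also set against the joint treatment, as 1 ligand of both receptors against a pair of ligands. Concentrations are not given in the labels, so matched receptor occupancy cannot be assumed. With the library set term 1 gene passed: Cyp26b1 fell by 3.03 ± 0.28 on the log2 scale (8.19-fold lower with 9-cis retinoic acid, edgeR FDR = 0.000574). In the 10-library set the log2 difference was -3.09 and did not pass (FDR = 0.0916), and in the 5-library pair it was -2.91. Angptl4 had a log2 difference of -2.31 ± 0.34 (FDR = 0.0638), Cpt1a of -0.83 ± 0.13 (FDR = 0.115) and Dhrs3 of -0.35 ± 0.21 (interval -0.80 to 0.10). Rarb had -0.14 (interval -0.98 to 0.69). Liver X receptor targets were lower with 9-cis retinoic acid (17 of 24 folds below 0, camera adjusted p = 1.2e-09, and adjusted p = 0.0051 with an estimated correlation, or 0.056 with the term as well), and PPAR targets were lower (21 of 30, adjusted p = 2.7e-05, and adjusted p = 0.027 with an estimated correlation, or 0.079 with the term as well). Adjusted over the list alone with the term, 7 and 6 members fell, and 0 over all genes. Without the term 0 genes passed, with 173 at an unadjusted p under 0.05 and 0 by DESeq2.

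Against AM580 alone, 9-cis retinoic acid gave 0 calls in either fit, with 126 and 241 genes at an unadjusted p under 0.05 in edgeR and 0 by DESeq2. Cyp26b1 had a log2 difference of 1.21 (95% interval 0.62 to 1.80 before adjustment), Dhrs3 of 0.30 (-0.15 to 0.76), Fmo5 of 0.14 (-0.26 to 0.54), Enpp1 of 0.10 (-0.18 to 0.38) and Rarb of 0.51 (-0.33 to 1.35) with the term. AM580 against CD3254 gave 0 calls without the term (153 genes at an unadjusted p under 0.05, and 1 by DESeq2) and 2 with it. Dhrs3 was 4.02-fold higher with AM580 (FDR = 0.00511) and Angptl4 was 7.51-fold lower (log2 change -2.91 ± 0.34, FDR = 0.00607), a call that ended without AM580 replicate 3 (FDR = 0.0990). The count was 3 without AM580 replicate 1 or CD3254 replicate 1. For Rarb the difference was 2.32 ± 0.44 (FDR = 0.424, and 0.0188 in the 10-library set, where it passed) and for Abcg1 -0.98 ± 0.15 (FDR = 0.0791).

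Fold changes were also compared between treatments across all genes tested. The change with CD3254 in cells without AM580 and in cells with it, which share no library, correlated at a Pearson r of 0.078 over 16736 genes, and the change with AM580 without and with CD3254 at -0.038. Over genes with a mean of at least 10 CPM the values were 0.361 and 0.118, and leaving out 1 library moved them between -0.110, without DMSO replicate 2, and 0.217, without DMSO replicate 3, and between -0.159 and 0.0414, without joint replicates 1 and 3. Leaving out 1 of the libraries compared also unbalances the library sets in these fits without the term, which may itself move the values. Genes are not independent replicates, so no p is given. The changes with 9-cis retinoic acid correlated with those of AM580, CD3254 and the joint treatment at 0.402, 0.453 and 0.528, but these pairs share the DMSO libraries. Unchanged groups, with all 15 libraries redrawn from the fit with the term, gave 0.492, 0.496 and 0.483. Their shared controls were simulated and are not the DMSO libraries themselves. No simulated library differs from the others as replicate 3 of 9-cis retinoic acid does. The covariance exceeded the simulated one by 0.00597, 0.00116 and 0.0222. With the term, the called genes shared between 9-cis retinoic acid and the other treatments numbered 4 of 5 for AM580, 1 of 4 for CD3254 and 5 of 21 for the joint treatment, where independent lists would share 0.00149, 0.00120 and 0.00627, and 0 were shared in the simulations. The first values leave out the shared controls, and simulated groups hold no changed genes to share, so neither is a reference for the overlap. The 3 control libraries are too few to split, so part of the overlap may come from the shared controls.

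Interferon-stimulated genes were lower in all 4 comparisons with DMSO at the preset correlation. With the joint treatment 22 of 24 measured members had folds below 0 and the median log2 change was -0.55 (camera adjusted p = 2.1e-14, and adjusted p = 0.0057 with an estimated correlation). With AM580 20 members lay below 0, at a median of -0.32 (adjusted p = 6.0e-06, and adjusted p = 0.064 with an estimated correlation), with 9-cis retinoic acid 23, at -0.32 (adjusted p = 1.7e-07, and adjusted p = 0.032 with an estimated correlation, or 0.11 with the term as well), and with CD3254 20, at -0.17 (adjusted p = 0.0080, and adjusted p = 0.30 with an estimated correlation). The call for CD3254 ended without DMSO replicate 1 or 2 or CD3254 replicate 1 (adjusted p up to 0.327). The list was also lower in the joint treatment than with CD3254 alone (adjusted p = 5.6e-09, and adjusted p = 0.025 with an estimated correlation, or 0.095 with the term as well). No member passed over all genes. Adjusted over the list alone with the term, the double-stranded RNA sensor gene Ddx58 fell with AM580 (by 0.73 on the log2 scale), Oas2, Mx2, Irf7, Oasl2 and Rtp4 fell with the joint treatment, and Ifih1 and Oas2 with 9-cis retinoic acid. Oas2, for an oligoadenylate synthetase, stood at 6.66 ± 0.898 CPM in DMSO and 4.0 ± 0.54 CPM with both agonists.

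The receptor genes Rara, Rarg, Rxra and Rxrb did not pass in any of the comparisons with DMSO. Rara stood at 18.7 ± 5.48 CPM in DMSO, Rarg at 31.7 ± 9.10, Rxra at 81.4 ± 8.79 and Rxrb at 102 ± 15.5, and the log2 changes of these 4 genes with the library set term lay between -0.21 and 0.25. Rxrg and Cyp26a1, at means of 0.00845 and 0.0453 CPM in DMSO, were below the filter and were not tested. Of the acinar and ductal genes named in advance, Cpa1, Ptf1a, Sox9 and Krt19 did not pass either. Cpa1, which encodes a pancreatic carboxypeptidase, stood at 547 ± 167 CPM in DMSO and had log2 changes between -0.41 and 0.24. The acinar transcription factor gene Ptf1a, at 46.0 ± 19.7 CPM, ranged from -0.08 to 0.28, the ductal and progenitor gene Sox9, at 33.7 ± 13.9 CPM, from -0.09 to 0.20, and the ductal keratin gene Krt19, at 1.91 ± 1.62 CPM, from -0.01 to 1.32. Stra6 and Tgm2 had log2 changes of up to 1.39 and 1.46, with SE values of 0.98 and 0.56, and did not pass over all genes.

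Of the other lists fixed beforehand, ductal and progenitor markers were higher at the preset correlation with AM580, the joint treatment and 9-cis retinoic acid against DMSO and with the joint treatment against CD3254, with adjusted p = 0.13, 0.11, 0.13 and 0.067 with an estimated correlation. Nuclear receptors and cofactors were higher with the joint treatment and with 9-cis retinoic acid, with adjusted p = 0.20 and 0.27 with an estimated correlation. The unfolded protein response was higher with AM580 and with 9-cis retinoic acid (adjusted p = 0.39 and 0.41 with an estimated correlation), cholesterol synthesis was higher with AM580 (adjusted p = 0.82 with it), Hox genes and immediate early and heat shock genes were lower with CD3254 (0.59 and 0.79), mitochondrially encoded transcripts were higher with 9-cis retinoic acid (0.83), and stellate and fibroblast markers were higher in 9-cis retinoic acid than in the joint treatment (0.52). Each of these calls except that of nuclear receptors in the joint treatment against CD3254 was lost in 3 to 5 of the 6 fits with 1 library left out, at adjusted p values of up to 0.103 to 0.902. Acinar enzymes, acinar transcription factors, endocrine markers, leukocyte and endothelial markers, targets of other RXR partners, the cell cycle, and readouts of TGF-beta, Wnt and Notch signalling gave no call in any of 8 contrasts, with smallest adjusted p values of 0.117, 0.194, 0.155, 0.142, 0.545, 0.256 and 0.117.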

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

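The tests below on the 9-cis retinoic acid library and those with the library set term were chosen only after the results were seen, and the other splits of the libraries in the fits without the term were planned. Groups of 3 libraries were too small to test for a library far from the others, so the values here are shares of reads counted in no gene that were more than 2 times that of the highest DMSO library. Smaller excesses over DMSO are not listed, such as 11.1% of reads outside genes in replicate 2 of the joint treatment and 11.4% aligned to several places in replicate 3 of 9-cis retinoic acid. In replicate 3 of 9-cis retinoic acid, 25.1% of reads lay outside genes against at most 8.47% in DMSO, and 6.82% lay over several genes against at most 3.10%. In the same library 4.51% of reads had a low mapping quality, against at most 1.29%, and 15.1% were not aligned, against at most 1.39%. In replicate 2 of the joint treatment 3.12% of reads were not aligned.

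Replicate 3 of 9-cis retinoic acid also held 10.6% of its gene counts on Gm42418, an rRNA-like gene, and 4.10% on Lars2. Its lower depth is argued against as the cause: the other libraries thinned to its depth kept a median correlation of at least 0.981 with the rest, and it had 0.962. Trends in GC content and transcript length explained 12% of its difference across genes, so they were not the whole of it. Cluster histone genes, whose transcripts lack a poly(A) tail, stood higher in it by a median of 4.21 on the log2 scale over 38 genes, above the highest of 10000 random lists at 0.842, and by 4.20 after those trends were removed, so RNA without a poly(A) tail carried into this library is a candidate explanation. The untailed RNAs Rmrp at 3.76 CPM and Rpph1 at 26.9 CPM did not stand above the other libraries of the 10-library set. Those ranged from 0 to 7.66 CPM for Rmrp and from 0.129 to 29.1 CPM for Rpph1. With ranges so wide, these RNAs speak neither for this explanation nor clearly against it, and no biological explanation was tested.

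Other splits of the same libraries were counted for each contrast. A comparison of 3 libraries with 3 has 10 splits, so the share is never under 0.1 and is too coarse for a test at 0.05. With the library set term the real split gave 5 calls for AM580, 4 for CD3254, 21 for the joint treatment and 5 for 9-cis retinoic acid against DMSO, 2 and 5 for the joint treatment against AM580 and CD3254, 1 for 9-cis retinoic acid against the joint treatment and 2 for AM580 against CD3254, and the highest of the other splits gave 0 in each. In these 8 contrasts 1 split, the real one, reached its own count. The other splits mixed both treatments in each group, so a gene that responds would widen the spread there. The 0 calls of those splits are thus partly built in. Without the term the joint treatment against DMSO gave 3 and the highest other split 0, again 1 split of 10. In the other 8 contrasts of that fit, and for 9-cis retinoic acid against AM580 with the term, all 10 splits gave 0. For the interaction, where 100 splits were drawn, the real split gave 0 in both fits, and since every count reaches 0, all 100 were as large by construction and say nothing about chance. There the highest other split gave 0 with the term and 3002 without it. A count so far above the real one may point to a structure of the samples, but this was 1 split of 100. The same split gave 0 calls with the term, so its calls depended on leaving the library set out of the model. No further structure was identified. That split put 3 of the 5 libraries that stand apart into 1 group, but 7 other splits did so too and gave 0, so this grouping alone does not account for it.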

How the results depend on the processing

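No named gene changed direction between the planned fit and an alternative where it passed in either, and no called gene list passed in the other direction, but the number of genes called depends on the setting. Values that did not pass did change sign, such as Cpa1 with AM580 (-0.40 on the log2 scale in the 10-library set). So did 2 called lists where they lost their call: cholesterol synthesis with AM580 without AM580 replicate 1 (adjusted p = 0.493) and mitochondrially encoded transcripts with 9-cis retinoic acid without its replicate 3 (0.775) or DMSO replicate 1 (0.902), and both without the pair AM580 replicate 1 and 9-cis retinoic acid replicate 3 (0.548 and 0.818). The median tagwise biological coefficient of variation was 0.305 without the term and 0.193 with it, and replicate 3 of 9-cis retinoic acid, at 14600962 counts, has the lowest depth. Of 202 values of named genes, the term left 161 with their sign and side of the threshold, 31 came past it and 10 that did not pass changed sign, and DESeq2 size factors changed none of the 202. Some of these genes were named because they passed with the term, so the 31 is partly built in. With 1 library left out, 1135 values kept both, 172 that did not pass changed sign and 13 lost their call. The alternatives in this part with the term, the 10-library set, the libraries left out as a pair and the GC and length offsets were chosen after seeing the data. Unless a smaller number of libraries or genes is named, the cause was not tested.

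In the fit without the term, calls against DMSO were 0 for AM580, 0 for CD3254, 3 for the joint treatment and 0 for 9-cis retinoic acid, and 0 in all other contrasts. Adding the library set term gave 5, 4, 21 and 5 against DMSO, 2 and 5 for the joint treatment against AM580 and CD3254, 1 for 9-cis retinoic acid against the joint treatment and 2 for AM580 against CD3254. The 10-library set alone gave 3 for AM580, 13 for the joint treatment and 4 for 9-cis retinoic acid, 2 and 5 for the joint treatment against AM580 and CD3254, and 3 for AM580 against CD3254. GC and length offsets gave 1 for AM580, 6 for the joint treatment, 1 for 9-cis retinoic acid and 1 for the joint treatment against CD3254. Without AM580 replicate 1 and 9-cis retinoic acid replicate 3 there was 1 call each for AM580, the joint treatment and the joint treatment against CD3254. The DESeq2 Wald test gave 10 for AM580, 19 for the joint treatment, 10 for 9-cis retinoic acid, 1 and 8 for the joint treatment against AM580 and CD3254 and 1 for AM580 against CD3254. For the joint treatment against DMSO a stricter filter on low counts gave 5 and a fit of only the groups compared, with fewer samples, gave 0. With 1 of the 6 libraries compared left out that count ran from 0, without DMSO replicate 1, to 2, without replicate 2 of the joint treatment. A library of another treatment also moved it, to 5 higher and 1 lower without AM580 replicate 1, 5 higher without CD3254 replicate 1 and 1 without AM580 replicate 2 or 9-cis retinoic acid replicate 3.

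Replicate numbers were not taken to pair the libraries, since not every pair with the same number varied together. Of 30 pairs with the same number, 20 had a correlation of deviations over 0.1, the range was -0.681 to 0.815, and 7 of 15 libraries correlated best with their own number. These deviations kept the difference between the library sets. Pairs within a set therefore tend to values above 0 and pairs across sets to values below 0, whatever their number. So the values neither show nor exclude pairing by number. The 8 values below 0 all involve replicate 1 or 2 of the joint treatment and are pairs across sets. The decision thus rests on the numbers as labelled, and an exchange of these 2 numbers is neither excluded nor was it tried. All 3 pairs exceeded 0.1 for DMSO with AM580, CD3254 and 9-cis retinoic acid and for AM580 with CD3254, whose replicate 1 is in the 5-library set. The replicate block gave 7 calls for the joint treatment against DMSO in place of 3, and 0 in each of the other contrasts, and with it the list of Hox genes with CD3254 did not pass (adjusted p = 0.069). These values also rest on the numbers as labelled, which put joint replicate 2, of the 5-library set, in a block with 4 libraries of the 10-library set and joint replicate 1 with 4 of the 5-library set.

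In the fit with the term, no filter on low counts gave 11 for AM580, 34 for the joint treatment, 9 for 9-cis retinoic acid and 8 for the joint treatment against CD3254. Leaving out AM580 replicate 1 and 9-cis retinoic acid replicate 3 gave 13 for CD3254, 109 for the joint treatment (81 higher and 28 lower) and 12 for 9-cis retinoic acid against DMSO, 13 for the joint treatment against CD3254, 7 for 9-cis retinoic acid against the joint treatment and 8 for AM580 against CD3254. DESeq2 gave 17, 13, 94 (62 higher and 32 lower) and 23 against DMSO, 13 and 17 for the joint treatment against AM580 and CD3254, 6 for 9-cis retinoic acid against the joint treatment and 14 for AM580 against CD3254. With 1 of the libraries compared left out the counts ran from 3 to 5 for AM580, 0 to 2 for CD3254, 11 to 17 for the joint treatment, 3 to 6 for 9-cis retinoic acid, 2 to 5 for the joint treatment against CD3254 and 1 to 3 for AM580 against CD3254, and stood at 1 for the joint treatment against AM580.

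Of 35 gene list calls at the preset correlation, 19 held with an estimated inter-gene correlation and 11 in the fry rotation test. The replicate block shared 34 of them, the term 33, the pair of libraries left out 27 and the 10-library set 26, and with 1 library left out 27 to 43 lists were called.

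The correlation of fold changes with CD3254, without and with AM580, was 0.361 over genes with a mean of at least 10 CPM, -0.0521 without the pair of libraries, -0.113 in the 10-library set, and from -0.110 to 0.217 with 1 library left out, so its sign depended on the setting. For AM580, without and with CD3254, it was 0.118 over genes of at least 10 CPM, -0.105 in the 10-library set, and from -0.159 to 0.0414, with the sign again not fixed. For 9-cis retinoic acid it was, with AM580, 0.20 without the pair, 0.253 in the 10-library set and 0.171 to 0.616 with 1 library left out; with CD3254, 0.313 over genes of at least 10 CPM and 0.204 to 0.683; with the joint treatment, 0.292, 0.352 and 0.259 to 0.723.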

Other observations

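The tests on both patterns below, including the setting of the interferon list against the CD3254 libraries, were chosen only after the results were seen.

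The levels of Itga2 and Tenm1 were looked at in each treatment after their changes with both agonists were seen. Itga2 stood at 1.82 ± 0.919 CPM in DMSO, 11.8 ± 2.04 with AM580, 5.30 ± 4.85 with CD3254, 33.4 ± 15.1 with both and 19.0 ± 10.1 with 9-cis retinoic acid (SD, n = 3), and passed over all genes with both agonists in the fit with the library set term. Tenm1 stood at 0.111 ± 0.0858 CPM in DMSO, 0.705 ± 0.127 with AM580, 0.366 ± 0.236 with CD3254, 3.33 ± 2.18 with both and 1.52 ± 1.01 with 9-cis retinoic acid. The FDR in edgeR for 9-cis retinoic acid against DMSO was 0.058 for Itga2 and 0.380 for Tenm1.

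The 5 libraries that stand apart on the first principal component were replicate 1 of 4 treatments and replicate 2 of the joint treatment. Trends in GC content and transcript length explained 1.14% of the difference across genes, which argues against them as the cause. Fibroblasts or stellate cells are argued against by collagen transcripts, the highest of which, over Col1a1, Col1a2 and Col3a1, reached 2.05 CPM in these 5 libraries, although Col1a1 stood higher there, at 1.56 to 2.05 CPM against 0.20 to 0.599 CPM in the other 10, while Col1a2 stood lower, at 0.298 to 1.01 CPM against 3.34 to 6.26 CPM. A list of 13 targets of the hypoxia-inducible factors already looked at had a gap of 2.49 between the sets. A list of 26 such targets, not looked at before, had library scores of 0.614 to 0.940 in the 5 libraries and -0.451 to -0.148 in the other 10. That gap of 0.762 on the log2 scale was reached by 0 of 10000 random lists, the highest being 0.211, so a state like that of low oxygen may set these libraries apart. The random lists were matched on expression but not on how genes vary together, and the set was read from the same counts. Other groups of genes that vary together could therefore exceed them too. Of these 26 genes 16 stood higher in each of the 5 libraries than in any other, while Pfkfb4 overlapped, at 8.54 CPM in the lowest of the 5 against 9.41 CPM in the highest of the other 10, and oxygen, density and culture day are not in the labels.

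Interferon-stimulated genes were lower in all 4 comparisons with DMSO at the preset correlation, and these share the 3 DMSO libraries, so a high level in those libraries could by itself give this pattern. Against the CD3254 libraries, which share none of them, the list was lower with the joint treatment when adjusted over these 3 comparisons alone (adjusted p = 0.0056 with an estimated correlation and 0.028 with the library set term as well), which the DMSO level does not account for. Adjusted over all tests of the 20 lists, the same comparison gave 0.025 and, with the term, 0.095, which does not pass, so the argument against the DMSO level holds for the narrower adjustment and is otherwise open. Against the same libraries the adjusted p was 0.12 for AM580 and 0.11 for 9-cis retinoic acid, and 0.17 for both with the term, so there the level of the DMSO libraries and an effect of the ligand cannot be told apart. The median log2 change with the joint treatment was -0.40 in the 10-library set and the 5-library pair differed by -0.59, and with AM580 the values were -0.40 and -0.11.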
